A study of Rattus norvegicus with 8 samples.

How the data were processed

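RNA of hippocampus and hypothalamus was enriched for polyadenylated transcripts and sequenced on an Illumina instrument, per the labels' protocols. The authors deposited FPKM values in 2 tables, one for each tissue, with a status column beside each library. The submitters' processing notes name TopHat, TopHat2, Bowtie, Bowtie2, Cufflinks and Cuffdiff and the rat build rn5; versions and options are not given in the sources used here. Each table numbers its own loci and holds no coordinates. The status columns held OK in nearly all cases, with 82 FAIL and 16 HIDATA among 72348 values for hippocampus and 44 and 12 among 71048 for hypothalamus. These flags mark loci for which the deposited value may be no full estimate.

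FPKM were summed over the loci of a symbol, which gave 16223 symbols for hippocampus and 16183 for hypothalamus. Of these, 15892 were in both tables, 331 only in that of hippocampus and 291 only in that of hypothalamus. For 13580 symbols there was 1 locus in both. Each library was scaled by a median-of-ratios factor over the shared symbols. The factors were 0.892, 0.911, 0.947 and 0.950 for hippocampus and 1.12, 1.07, 1.08 and 1.09 for hypothalamus. Values within a tissue used factors computed within its own table. Genes with a mean of at least 1 FPKM over the 8 libraries were compared (10554 genes) on the scale of log2(FPKM + 1), which understates differences of low genes. A gene was called higher or lower when its mean difference was at least 1 and the 4 libraries of a tissue did not overlap with those of the other.

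The comparison was first planned as a limma test with a mean-variance trend, to be replaced by levels side by side if the tables proved to be normalised apart by more than a factor per library. That model was fitted, and gave 1455 genes higher and 1431 lower in hypothalamus at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 1. Levels side by side were chosen only after these counts had been seen, together with ubiquitous genes such as Gapdh at FPKM far apart between the tables. Tissue and table coincide, so the model's p-values measure the spread between libraries and cannot part a tissue difference from a table difference. Both routes called 2808 genes in the same direction, limma alone 78 and separation alone 8. Camera was run on the lists with a preset correlation of 0.01 and with an estimated one, and fry was run as well; no statement rests on fry.

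Gene lists (27, members matched by symbol) were fixed before the data were examined, as were the main comparison, most of the other settings and the rule for named genes. Some lists shared members, so their results are not independent of each other. Lists with at least 5 measured members were used, 25 in the tissue contrast; the blood cell list and the list of Y-linked genes with Xist had too few. A list's median difference was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins, and called outside when it lay under percentile 2.5 or over 97.5. Counts of members called by limma over all genes and adjusted over the list alone differed for 2 lists: matrix genes (10 higher over all genes and 11 adjusted over the list alone) and choroid plexus markers (1 lower and 0 adjusted over the list alone). Spread within a tissue was the SD of log2(FPKM + 1) over 4 libraries for genes with a mean of at least 5 FPKM there, placed among random lists in the same way. The genes named were the 8 largest differences in each direction among called genes, from each list the 2 called members with the largest difference and the 2 members with the highest level, in each tissue the 5 highest means, and in each tissue the 5 largest SDs; some genes that this rule names are not reported here. Genes listed per library for the pineal gland, dopamine neurons and histocompatibility, and the families of ubiquitous genes, were chosen after their values had been seen, as was Khk, named because it lies in 1 table.

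The number of reads was unknown. For loci under 0.05 FPKM in both of 2 libraries, ratios fell on a shared value or a small multiple of it (within 0.01 on the natural log scale) for 85.8 to 92.0% of loci in each of the 6 pairs among replicates 2, 3 and 4, and for 7.38 to 10.6% in the 6 pairs with replicate 1. The steps give relative depth among replicates 2, 3 and 4 of a tissue, and no absolute depth. Correlation between libraries of a tissue, across genes, was 0.923 to 0.973 for hippocampus and 0.951 to 0.989 for hypothalamus, and no pair held identical values above 0.

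The calculations were tested on simulated tables of 10554 genes. For the tissue contrast, 93% of genes with a true log2 change of 1.5 and 99% of those with 3 were recovered, and 0.0773% of unchanged genes were called. The limma model recovered 91% and 99%. A simulated list of 20 genes shifted by 0.8 lay at percentile 100, and 4 of 100 unshifted lists lay outside the range. The simulated tables differed by scaling factors and the planted changes only, and their genes varied independently. These rates therefore do not cover differences between the tables at single genes, or genes that vary together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used. The reference gene table (assembly GRCr8) served only for the order of genes along chromosomes, since its build differs from rn5.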

Results

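Gene expression was measured by RNA sequencing in the hippocampus and the hypothalamus of male Sprague Dawley rats, an outbred laboratory strain. The animals were 2 months old when the diet began and received 15% fructose in the drinking water together with a diet rich in omega-3 fatty acids for 6 weeks. Docosahexaenoic acid (DHA), the omega-3 fatty acid named for this arm, is a major lipid of neuronal membranes. There were 4 libraries from each tissue, 8 in all, and every library came from this diet arm. The effect of fructose or of DHA therefore has no comparison here, and libraries of other arms were not analysed here. The labelled contrast was hypothalamus against hippocampus. Values were FPKM, fragments counted relative to transcript length and sequencing depth, with 18087 loci listed for hippocampus and 17762 for hypothalamus. The number of reads per library was unknown. Low values showed the relative depth of 3 libraries per tissue: a single fragment was worth 1.36 times as much in hippocampus replicate 2 as in replicate 3, and 1.07 times as much in replicate 3 as in replicate 4. In hypothalamus the corresponding ratios were 0.931 and 1.05. Replicate 1 of each tissue did not share these steps. The labels do not say whether each library came from a separate animal, so the spread given below is that between libraries.

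The hypothalamus libraries were marked by neuropeptide and hypothalamic transcription factor genes. Most genes of pallial glutamatergic neurons were higher in hippocampus, a list with an adjusted p = 0.207 with an estimated correlation in limma's camera. Of 10554 genes compared, 1402 were at least 2-fold higher on the log2(FPKM + 1) scale in hypothalamus with no overlap between the libraries of the tissues, and 1414 were lower by the same measure. Libraries did not overlap for 53.4% of the genes, whereas chance gives 2.86% for 4 against 4. The tissues were listed in separate tables, and some genes used by every cell differed widely between the tables, so levels were set side by side. Genes were called by separation of the libraries and lists were placed among random lists, and p-values of limma across the tables stand beside these. With values as deposited, 1912 genes were higher and 1018 lower, or 65.3% of these genes higher, and the median gene lay at 0.18 in place of -0.04 after joint scaling. Upper-quartile scaling placed the median gene at 0.07. With only symbols of 1 locus in each table kept (8717 genes), 1188 were higher and 1005 lower, or 54.2% of these calls higher. Symbols summed over several loci numbered 1743 for hippocampus and 1472 for hypothalamus, so the balance of the main counts depended on them. All differences below are relative to the joint scaling.

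Most neuropeptide genes of the hypothalamus were higher there. Of 25 measured members, 19 were higher in hypothalamus, 2 were lower and 4 were neither, and the median difference of 2.87 lay above all 10000 random lists matched on level. Avp, which encodes the antidiuretic hormone vasopressin, reached 4260.3 ± 2519 FPKM in hypothalamus (SD, n = 4) and 0.13 ± 0.11 in hippocampus, a log2 difference of 11.68 ± 0.45 (SE). Oxt, encoding oxytocin, stood at 1899 ± 218 FPKM against 0.10 ± 0.15. Pmch, encoding melanin-concentrating hormone of lateral hypothalamic neurons, stood at 790.0 ± 307 against 0.64 ± 0.22. Hcrt, encoding the orexins, stood at 595 ± 174 against 4.52 ± 3.28. Camera in limma placed the list higher with an adjusted p = 0.0358 with an estimated correlation. The median was 4.35 with a pseudocount of 0.1.

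Hypothalamic transcription factor genes followed the same direction, with 20 of 23 members higher, 1 lower and a median difference of 1.94, above all 10000 random lists. Lhx1, a LIM homeobox gene, was at 53.2 ± 5.82 FPKM in hypothalamus and 0.07 ± 0.04 in hippocampus. Otp, required for neuroendocrine neurons, was at 14.1 ± 4.35 against 0.02 ± 0.04. Arnt2, the member with the highest mean level over the libraries, was at 32.7 ± 5.74 against 26.8 ± 5.99 FPKM, a difference of 0.28 ± 0.21, and its libraries overlapped. The adjusted p = 0.00984 with an estimated correlation in limma's camera. The median was 4.16 with a pseudocount of 0.1 and 3.32 with a filter at a mean of 5 FPKM.

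Genes of hippocampal and pallial neurons were lower in hypothalamus for 21 of 23 members, and the other 2 were neither higher nor lower. Their median difference of -2.93 lay below all 10000 random lists. In limma's camera the adjusted p was 6.98e-10 with the preset correlation and 0.207 with an estimated one. Slc17a7, the vesicular glutamate transporter of cortical and hippocampal excitatory neurons, was at 767 ± 236 FPKM in hippocampus and 0.50 ± 0.37 in hypothalamus, and both it and Camk2a carried a status flag in at least 1 library. Itpka, an inositol trisphosphate kinase of dendritic spines, was at 217 ± 61.9 FPKM in hippocampus against 1.32 ± 0.26. Neurod6, a transcription factor of pallial neurons, was at 85.7 ± 21.0 against 0.97 ± 0.41. Camk2a, the calcium/calmodulin kinase of excitatory synapses, was at 1714 ± 390.2 against 119 ± 38.2. Ddn, encoding the dendritic protein dendrin and on no list, was at 306 ± 127 against 4.90 ± 2.43. Of 13 subfield genes, 8 were lower in hypothalamus and 1 higher, with Wfs1, a gene of the CA1 field, at 146 ± 30.7 FPKM in hippocampus against 16.1 ± 2.66 in hypothalamus and Rgs14, a gene of the CA2 field, at 36.8 ± 7.29 against 2.66 ± 0.42. The subfield list had an adjusted p = 0.401 with an estimated correlation. Its median of -1.40 was -0.83 without a filter, and also with 1 locus per table. The subfield list shares members with the pallial list, Wfs1 and Rgs14 among them.

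**Figure D1:**
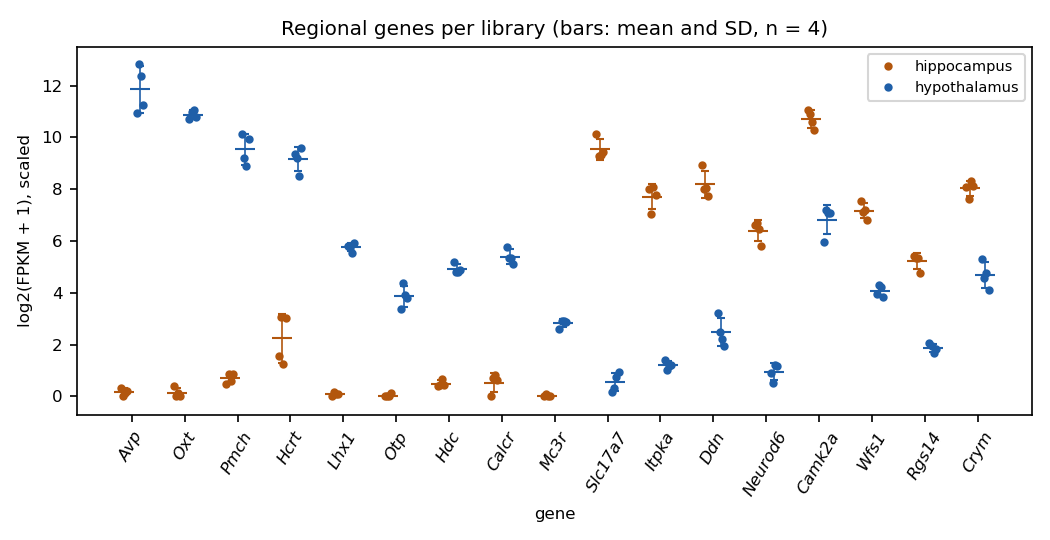
Level of regional genes in each library, as log2(FPKM + 1) after joint scaling, for hippocampus and hypothalamus. Points are the 4 libraries of a tissue, the horizontal mark is their mean and the bar their SD; Avp averaged 4260.3 FPKM in hypothalamus against 0.13 in hippocampus, and Slc17a7 averaged 767 in hippocampus against 0.50 in hypothalamus.

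Some genes of each transmitter system separated the tissues. GABA neuron genes were higher in hypothalamus for 7 of 15 members, lower for 1 and neither for 7, with a median of 0.96 at percentile 99.9 of the random lists and an adjusted p = 0.0985 with an estimated correlation in limma's camera. The list shares the Dlx genes and Lhx6 with the hypothalamic transcription factors, and Sst and Vip with the neuropeptide genes, so it is no separate evidence. Gabrq, the theta subunit of the GABA-A receptor, was at 14.8 ± 1.42 FPKM in hypothalamus against 0.19 ± 0.17 in hippocampus, while Sst, encoding somatostatin, was at 370 ± 88.8 against 266 ± 83.5 and did not separate. Glutamate signalling genes were lower for 10 of 23 members and higher for 1, with a median of -0.77 at percentile 0.11, which moved to -0.46 and percentile 3.31 when only symbols with 1 locus in each table were kept. The adjusted p was 0.411 with an estimated correlation. Among monoamine and histamine genes, 6 of 16 were higher and 1 lower, with an adjusted p = 0.229 with an estimated correlation. Hdc, the histamine-forming enzyme, was at 29.5 ± 4.41 FPKM against 0.41 ± 0.13, and Th, which limits the rate of catecholamine synthesis, was at 29.7 ± 15.6 against 0.86 ± 0.27. The monoamine list's percentile of 98.4 fell to 96.5 without a filter on low values, to 97.2 without replicate 1 of hippocampus and to 96.4 without replicate 1 of both tissues.

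The lists of synaptic plasticity and immediate early genes, which share Arc and Egr1, had medians below all random lists, but neither was called by limma's camera with an estimated correlation. Of 23 plasticity genes, 11 were lower in hypothalamus, 3 higher and 9 neither, with an adjusted p = 0.411 with an estimated correlation. Their median of -0.96 moved to -0.38 and percentile 5.19 with 1 locus per table. Nrn1, encoding neuritin, was at 24.2 ± 3.21 FPKM in hypothalamus against 300.2 ± 68.9 in hippocampus. Of 17 immediate early genes, 9 were lower, none was higher and 8 were neither, with an adjusted p = 0.466 with an estimated correlation. Their median of -1.58 was -0.86 with a filter at a mean of 5 FPKM. Arc, a synaptic immediate early gene, was at 4.06 ± 1.25 FPKM in hypothalamus against 54.9 ± 21.7, Egr3 at 1.45 ± 0.48 against 32.4 ± 5.82 and Nr4a1 at 9.24 ± 1.88 against 82.3 ± 34.5. Egr1 overlapped between the tissues, with a difference of -0.85 ± 0.44, and separated at -1.03 without hippocampus replicate 3. The plasticity list was lower in hypothalamus replicate 1, at a median log2 level of 6.32, than in the others, at 6.92 to 6.94.

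Most genes that handle fructose, glucose and long-chain fatty acids, the nutrients of this diet, did not separate the tissues by the measure used, and equality was not tested. By that measure 13.3% of all genes compared were higher in hypothalamus and 13.4% lower. Of 26 measured fructose and glucose genes, 3 were higher in hypothalamus, 1 was lower and 22 were neither, and the median difference of 0.04 lay at percentile 61.0. Aldoa and Aldoc, glycolytic aldolases, were at 858 ± 41.6 and 856 ± 84.0 FPKM in hypothalamus and at 1321 ± 393 and 717 ± 186 in hippocampus. Gapdh, a glycolytic enzyme of every cell, was listed at 581 ± 125 FPKM in hypothalamus and 6.19 ± 1.66 in hippocampus (log2 difference 6.34), in tables where 20 of 75 ribosomal protein genes were also at least 4-fold apart. Khk, the first enzyme of fructose breakdown, was listed for hippocampus only, at 4.11 ± 1.60 FPKM. Pkm and Elovl1 were likewise not listed for hypothalamus, so a missing entry there is not read as missing expression. Of 27 genes for long-chain fatty acids and DHA, 1 was higher, 1 was lower and 25 were neither, with a median of 0.02 at percentile 66.9, while limma's camera with an estimated correlation pointed down (adjusted p = 0.991). Fads2, a desaturase on the route to DHA, was at 139 ± 14.8 FPKM in hypothalamus and 87.5 ± 26.7 in hippocampus, and Fabp7, a fatty acid binding protein of glia, at 160 ± 25.3 and 101 ± 22.0. Rxrg, encoding a retinoid X receptor, was at 17.8 ± 2.27 against 6.78 ± 2.70, and Ptgs2, encoding cyclooxygenase 2, at 1.02 ± 0.39 against 14.9 ± 5.66. With values as deposited the medians were 0.25 for the fructose and glucose list and 0.24 for the fatty acid list. The former was 0.18 without hypothalamus replicate 1 and the latter 0.19 without hippocampus replicate 4. Cholesterol synthesis genes had a median difference of -0.01 (0.22 with values as deposited), with 2 higher, 4 lower and 11 neither of 17. Mvd was at 35.4 ± 6.53 FPKM in hypothalamus against 9.12 ± 4.46, Nsdhl at 59.4 ± 3.15 against 14.8 ± 1.93, and Hmgcs1 at 74.4 ± 24.6 against 158 ± 28.8, although Hmgcs1 stayed under the 2-fold limit with values as deposited (-0.87), with upper-quartile scaling (-0.99) and without replicate 2 of hippocampus, where it was -0.999.

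**Figure D2:**
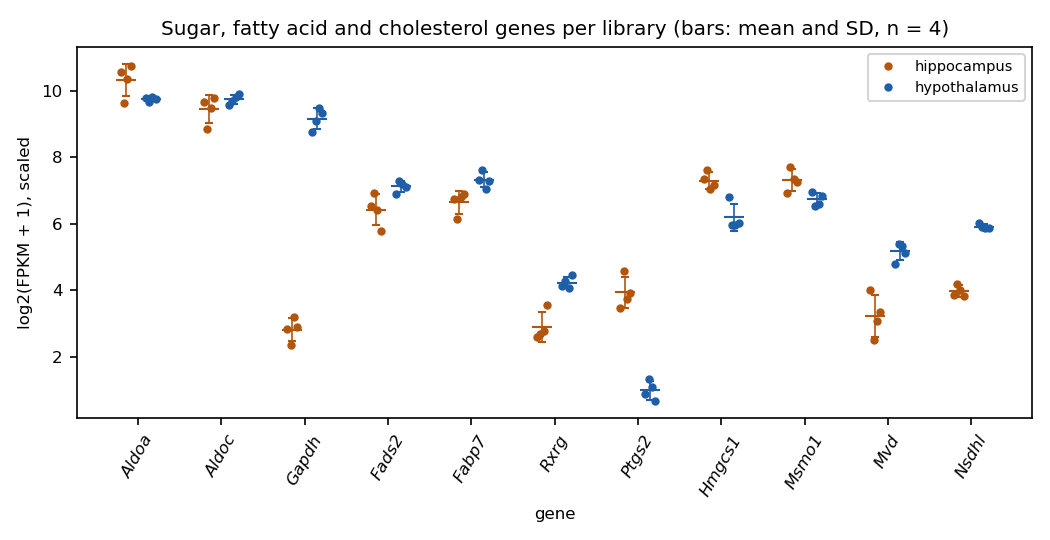
Level of sugar, fatty acid and cholesterol genes in each library, as log2(FPKM + 1) after joint scaling. Points are the 4 libraries of a tissue, the horizontal mark is their mean and the bar their SD; Fads2 averaged 139 FPKM in hypothalamus and 87.5 in hippocampus, while Ptgs2 averaged 1.02 and 14.9.

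Receptors of energy balance and hormones went both ways, with 4 of 27 higher in hypothalamus, 5 lower and 18 neither. Calcr, the calcitonin receptor, was at 41.9 ± 8.75 FPKM in hypothalamus against 0.48 ± 0.33 in hippocampus, and Mc3r, a melanocortin receptor, at 6.11 ± 0.72 against 0.01 ± 0.03. Thra, a thyroid hormone receptor, was at 109 ± 13.2 against 222 ± 45.6, and its difference of -1.01 fell short of the limit at -0.78 with values as deposited, -0.89 with upper-quartile scaling, -0.97 with quantile normalisation, -0.92 without hypothalamus replicate 1, -0.89 without hippocampus replicate 1 and -0.80 without both. The list's median of -0.35 lay at percentile 2.05, and this position moved inside the range of random lists with a pseudocount of 0.1 (percentile 2.71), without hippocampus replicate 1, 3 or 4 (2.97, 3.61 and 8.45) and with 1 locus per table (8.27). The median was -0.82 with a filter at a mean of 5 FPKM, -0.16 with values as deposited, -0.22 without hippocampus replicate 4 and -0.18 with 1 locus per table. Its adjusted p was 0.949 with an estimated correlation in limma's camera.

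The lists of extracellular matrix, vascular wall and ventricular lining genes had medians above the random range, but none of the 3 was called by limma's camera with an estimated correlation. Of 22 matrix genes, 9 were higher in hypothalamus, 3 lower and 10 neither, with an adjusted p = 0.553 with an estimated correlation. Their median of 1.04 lay above all random lists and was 0.54 without a filter. Sparc, a collagen-binding matrix protein, was at 1213 ± 270 FPKM in hypothalamus against 391 ± 53.1 in hippocampus, and Col3a1, a fibrillar collagen, at 19.0 ± 3.68 against 2.47 ± 1.35. Hapln1, a link protein of hyaluronan matrix, went the other way at 1.47 ± 0.12 against 11.4 ± 4.38. Mural and meningeal markers were higher for 3 of 10 members and neither for 7 (adjusted p = 0.401 with an estimated correlation). Tagln, a smooth muscle gene, was at 160 ± 57.3 FPKM against 32.9 ± 20.1. Acta2, on the same list, overlapped between the tissues, at 114 ± 45.4 FPKM in hypothalamus against 142 ± 89.1 in hippocampus. Ependymal and tanycyte markers were higher for 8 of 14 and lower for 3 (adjusted p = 0.466 with an estimated correlation), with Vim, an intermediate filament of tanycytes, at 339 ± 68.8 against 44.7 ± 16.3. Crym, also on that list and a thyroid hormone-binding protein, was lower, at 25.9 ± 9.20 against 266 ± 50.2. These 3 lists also had wide spread between libraries of a tissue, given below.

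Glial and endothelial markers mostly did not separate the tissues, which held as well for all genes compared (13.3% higher and 13.4% lower). Of these markers, those of astrocytes were called most often. Astrocyte markers had a median of 0.53 at percentile 96.8, with 6 of 15 higher and 1 lower. Agt, encoding angiotensinogen, was at 892 ± 37.5 FPKM in hypothalamus against 65.9 ± 8.11, and Slc6a11, a GABA transporter, at 246 ± 40.1 against 37.6 ± 11.4. Leaving out hypothalamus replicate 2, 3 or 4 moved the astrocyte list above the random range, at percentiles 97.8, 98.3 and 98.2, while the adjusted p over all libraries was 0.401 with an estimated correlation in limma's camera. Replicate 1 of hypothalamus was the lowest for this list, at a median log2 level of 7.69 against 8.11 to 8.18, and for endothelial markers, at 2.99 against 3.88 to 4.01. Of 19 myelin markers 2 were higher and 17 neither, with Mbp at 3763 ± 900 FPKM in hypothalamus against 2045 ± 341 in hippocampus. Mbp passed the limit at 1.10 with values as deposited. Fa2h, a called myelin gene at 1.04, fell short of it without hypothalamus replicate 4 (0.88), hippocampus replicate 1 (0.98) or hippocampus replicate 4 (0.97). Of 15 microglia markers 3 were higher and 12 neither, with C1qb, a complement subunit, at 63.2 ± 12.2 against 15.4 ± 1.26. The microglia list moved from percentile 95.8 to 98.7 without hypothalamus replicate 1, to 99.1 without replicate 1 of both tissues and to 98.3 without hippocampus replicates 3 and 4. In limma's camera over all libraries it had an adjusted p = 0.0220 with the preset correlation and an adjusted p = 0.466 with an estimated correlation. The preset correlation called 9 lists higher and 5 lower, so this call was not particular to microglia. Of 12 endothelial markers 1 was higher, 3 were lower and 8 neither, and the lower call of Cldn5 was lost with values as deposited (-0.92). Of 7 oligodendrocyte precursor markers 1 was lower, Neu4 at -1.06, and it fell short of the limit with values as deposited (-0.87), with upper-quartile scaling (-0.97) and without hippocampus replicate 2 (-0.98). The median of this list was 0.11 while limma's camera pointed down (adjusted p = 0.949 with an estimated correlation). Thalamus and striatum markers were higher for 4 of 14 members and lower for 3. Pan-neuronal markers were higher for 4 of 15 and lower for 3, with Uchl1 at 2137 ± 183 FPKM in hypothalamus against 749 ± 126 and Syt1 at 191 ± 20.3 against 607 ± 92.3. Their median of -0.73 at percentile 1.54 turned to 1.02 with 1 locus per table, so no direction is given for this list. It lay inside the random range without hypothalamus replicate 1 (percentile 2.57) or hippocampus replicate 1 (3.40), and the adjusted p was 0.873 with an estimated correlation in limma's camera.

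**Figure D3:**
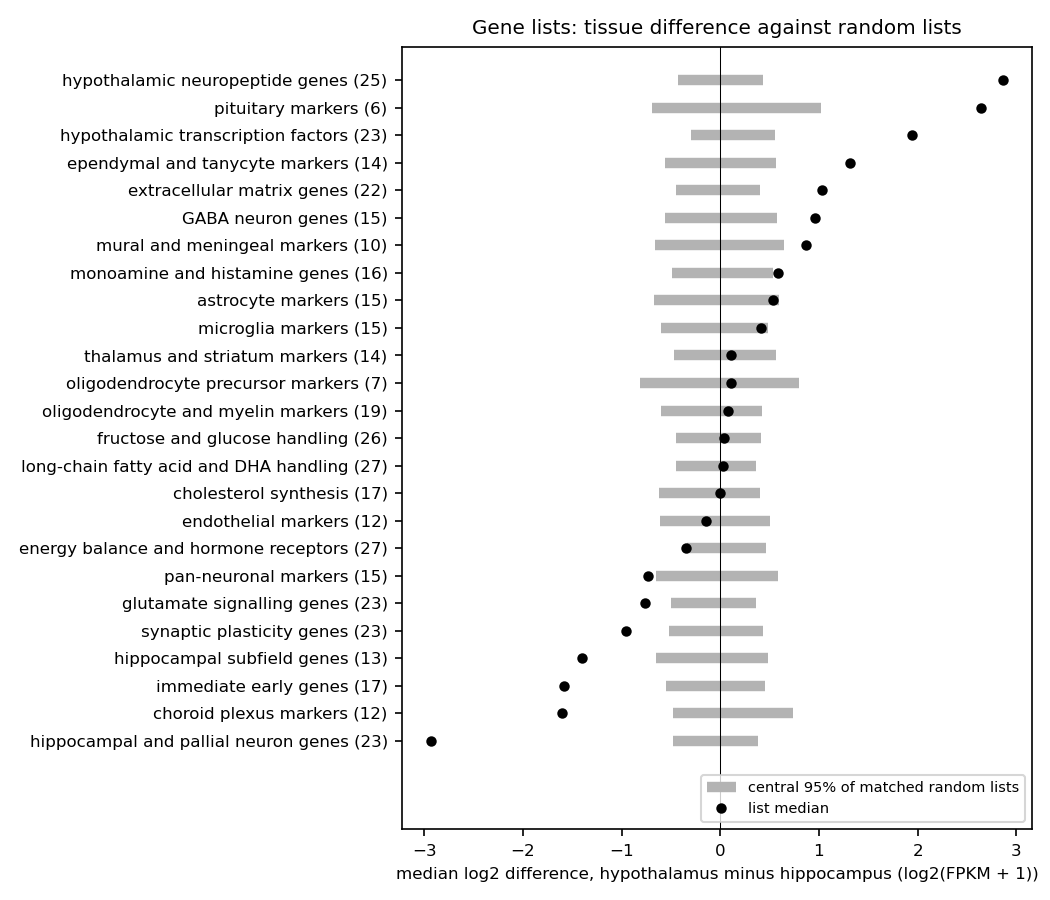
Median log2 difference, hypothalamus minus hippocampus, of each gene list (points), with the number of measured members in parentheses, over the central range of 10000 random lists matched on level (grey bars). Hypothalamic neuropeptide genes lay at 2.87 and hippocampal and pallial neuron genes at -2.93, while fructose and glucose handling lay at 0.04 and long-chain fatty acid and DHA handling at 0.02.

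Genes used by every cell were set beside the comparison, in families chosen after values had been seen. Of 75 ribosomal protein genes, 12 were at least 4-fold higher in hypothalamus and 8 at least 4-fold lower, although the median difference was -0.12. Over 284 genes of the ribosome, proteasome, respiratory chain, translation initiation and RNA polymerase families, 13.0% were at least 4-fold apart, against 6.93% of all genes compared. Several genes with the largest differences belonged to this kind or were on none of the lists. Tf was among the latter because the myelin list holds transferrin under another symbol, Trf. Rpl22l1 was at 2.31 ± 1.52 FPKM in hypothalamus against 219 ± 36.5 in hippocampus, Tf, encoding transferrin, at 448 ± 46.9 against 1.04 ± 0.66, Lpp at 0.50 ± 0.14 against 189 ± 27.7, Sdf4 at 0.41 ± 0.44 against 69.0 ± 14.4 and Plac8 at 441 ± 317 against 1.18 ± 0.70. Ugt2b1, of a family of near-identical genes, stood at 1068, 835, 1856 and 3127 FPKM in hippocampus replicates 1 to 4 and was listed at 0 in each hypothalamus library.

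Within hippocampus, the genes with the highest mean levels were Ubb, encoding ubiquitin (3283 ± 1079 FPKM), Tmsb4x, Ttr, Zwint and Mdh1. The widest spread between libraries was that of Ttr, the thyroxine carrier made by choroid plexus, at 35.6, 34.6, 6203 and 4617 FPKM in replicates 1 to 4. Choroid plexus markers had a median SD of 2.30 on the log2 scale, above all random lists. In the tissue contrast their median was -1.61 with none of 12 members separated, and it turned to 0.27 without hippocampus replicates 3 and 4. It was -2.45 without replicate 1, -0.79 without replicate 3 and -0.97 without replicate 4; the adjusted p was 0.873 with an estimated correlation in limma's camera. Ttr itself separated, at -5.27, without hypothalamus replicate 2. Gngt1 and Tph1, the latter the tryptophan hydroxylase of the pineal gland, stood at 125 and 137 FPKM in replicate 4 and at 1.63 or less in the other hippocampus libraries. Nxf3 and Tomm22 were near 0 in replicate 1, at 0.42 and 0, and at 31.1 or more in the others. Lists with a spread above the random range were 7 in hippocampus: choroid plexus, mural and meningeal (median SD 0.61), ependymal and tanycyte (0.54), thalamus and striatum (0.50), immediate early (0.42), pallial neuron (0.42) and subfield genes (0.40). This number was 13 without replicate 2. Without replicate 1 the pallial (percentile 92.2), subfield (88.9) and ependymal lists (84.7) lay inside the random range, as did the immediate early list without replicate 3 (97.1) and the subfield list without replicate 4 (83.2). The mural list lay inside it with a filter at a mean of 1 FPKM (93.8) or 1 locus per symbol (93.8), and the subfield list with 1 locus per symbol (82.6).

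**Figure D4:**
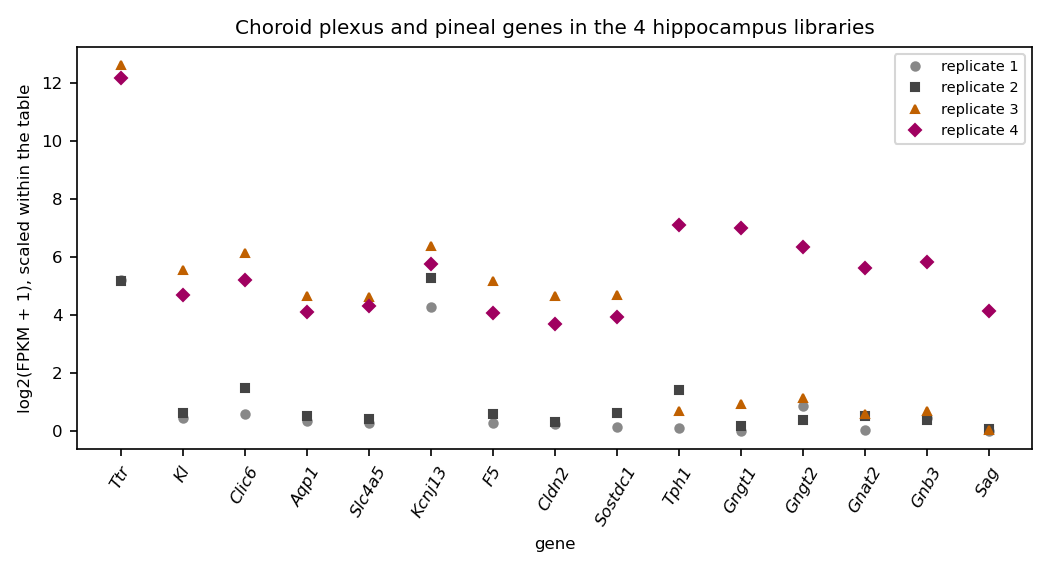
Choroid plexus genes (Ttr to Sostdc1) and pineal genes (Tph1 to Sag) in the 4 hippocampus libraries, as log2(FPKM + 1) scaled within the table, with a symbol for each replicate. Ttr stood at 6203 and 4617 FPKM in replicates 3 and 4 against 35.6 and 34.6 in replicates 1 and 2, and Tph1 at 137 FPKM in replicate 4.

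Within hypothalamus, the highest mean levels were those of Ptgds, a prostaglandin D synthase (7674 ± 3507 FPKM), Ubb (4914 ± 531), Avp, Gnas and Cst3. Among the widest spreads were those of LOC685322 and of the class I histocompatibility genes RT1-CE16 (0, 1910.4, 2758 and 0 FPKM in replicates 1 to 4), RT1-T24-2 and RT1-CE14. The histocompatibility genes belong to multigene families and are uncertain at the level of single genes. Neuropeptide genes had a median SD of 0.35, above the random range of 0.14 to 0.27. Matrix genes (0.34), mural and meningeal markers (0.46), ependymal and tanycyte markers (0.38) and pituitary markers (0.58) also exceeded their random ranges, 5 lists in all. This number was 9 without replicate 1, and the mural list lay inside the range without replicate 3 (percentile 78.7), as did the ependymal list with a filter at a mean of 1 FPKM (91.6). Fructose and glucose genes (0.17) and fatty acid and DHA genes (0.24) varied within the range of random lists in hypothalamus, as they did in hippocampus (0.27 and 0.34), although the fatty acid list passed it in hippocampus with values as deposited and without replicate 1 (percentile 98.4).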

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

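Tests of explanations in this part were chosen after the results were seen, apart from that of loci per symbol and that of numbering runs. Of 219 sets of 4 libraries, 23 held a library far from the other 3, against 10.9 that chance would give at 1 in 20. The sets come from the same 8 libraries and include genes named for their wide spread. The chance number is therefore a rough guide only.

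Hypothalamus replicate 1 accounted for 16 of these. Its level was low, with the gap to the nearest library as a share of the range, for Arnt2 (0.881), Camk2a (0.906), Cdh5 (0.863), Cspg5 (0.924), Egr3 (0.923), Gng7 (0.846), Mc3r (0.872), Sparc (0.910), Thra (0.856) and Cst3 (0.900). It was high for Calb1 (0.865), Hmgcs1 (0.914) and Rpl22l1 (0.859). The lists of synaptic plasticity genes (0.961), astrocyte markers (0.870) and endothelial markers (0.875) were low there. In hypothalamus replicate 3, Cpne4 was low (0.830), and in replicate 4 the hypothalamic transcription factors were high (0.918). In hippocampus, replicate 1 was high for Slc17a7 (0.831) and for hypothalamic transcription factors (0.860) and low for Nxf3 (0.947), and replicate 4 was low for Rgs14 (0.861) and high for Gngt1 (0.866).

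Replicate 1 of each tissue was near 0 at single loci that were well expressed in the other libraries. This held for 166 loci in hippocampus and 87 in hypothalamus, against at most 13 and 5 in any other library. A shallower or poorer library would affect symbols with several loci no more than others, but such symbols held 94.0% of the affected loci in hippocampus and 88.5% in hypothalamus, at least 4.92 times their share of all loci of that level. A fall of the whole symbol as deep as at its affected locus is argued against by the level summed over its loci. That level was 0.716 of that in the other libraries (median of 233 symbols). It was still below theirs, and the symbols were picked by a low locus, so a loss confined to the affected locus is not excluded. A candidate explanation is that reads of replicate 1 were assigned to loci in another way: the 2 loci of an affected symbol lay in different ascending runs of locus numbers on a chromosome for 80.5% (182 of 226), against 59.0% of other symbols with 2 loci, between the bounds set in advance, so this stays open.

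Choroid plexus genes stood at very different levels between hippocampus libraries, and pineal genes in replicate 4. For 100% of the 11 choroid plexus markers other than Ttr, the libraries with the highest levels were the same 2 as for Ttr (replicates 3 and 4), where chance gives 1 in 6. A change of Ttr alone is argued against by the median range of those markers, 4.37 on the log2 scale, and a scaling error by the libraries' median levels, which spanned 0.0566 on the log2 scale before scaling. Pineal tissue may be present in replicate 4: of 14 pineal genes not looked at before that list was written, 11 (78.6%) were at least 4-fold higher there than in each other hippocampus library, with Pdc at 30.2 FPKM, while Otx2, a gene of choroid plexus and pineal gland, was listed at 0 in each library. Tissue carried over in dissection is thus a hypothesis for both, found and tested on the same libraries.

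Of 284 ubiquitous genes, 37 were listed at least 4-fold apart in the tables of the tissues. A single factor per library or table cancels in the joint scaling, so the counts that follow are no test of it. More ribosomes in a tissue would move ribosomal protein genes one way. Against that as the whole cause, 12 of the ribosomal protein genes were at least 4-fold higher in hypothalamus and 8 at least 4-fold lower, each with no overlap of libraries. Symbols split over several loci were at least 4-fold apart 1.84 times as often (8 of 37) as those with 1 locus in both tables (29 of 247), which leaves most of the genes that lay 4-fold apart unaccounted for and the explanation open. Whether loci were bounded differently in the separate tables could not be examined without coordinates.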

How the results depend on the processing

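The settings of limma, scaling, filter, pseudocount and left-out single libraries were planned; those on loci per symbol, status flags, libraries left out together, a missing size limit, choroid plexus and pineal genes left out, and list levels were added afterwards. Called genes numbered 1358 to 1546 higher and 1380 to 1501 lower with any single library left out. Without a size limit the libraries of 2708 genes lay higher and of 2926 lower in hypothalamus; limma without it gave 3046 and 3179, since more genes can pass. The limma test as first planned gave 1455 and 1431 genes. Of the 35 splits of the 8 libraries, 1 reached the real total of 2886 limma calls and the highest other gave 0. A share of 1 in 35 is the lowest these splits can give, and each other split mixes the tissues. The splits thus speak against a random grouping for the total of limma calls and not for single genes. A table difference is not excluded.

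A replicate block in limma gave 1459 and 1439 genes. Same-numbered libraries deviated with correlations of -0.08, -0.06, 0.08 and 0.14 and 1 of 4 was the best match of its own number both ways, so the numbers do not show a pairing. Lists above the random range numbered 8 and below it 8 (7 to 9 and 6 to 8 with a library left out). Below were 4 lists with 1 locus per table. Camera as first planned called 9 lists higher and 5 lower, as it did with the block or without a trend. The 5 lower were the pallial, subfield, glutamate, plasticity and immediate early lists. With an estimated correlation camera called 2 lists higher and 0 lower. The cause was not tested. Among lists outside the random range in the main comparison, reversed were pan-neuronal markers (1.02, 1 locus per table) and choroid plexus markers (0.27 without hippocampus replicates 3 and 4, the libraries where those genes were high). Medians of some lists inside that range changed sign too, such as oligodendrocyte precursor markers, at -0.19 without hippocampus replicates 3 and 4. Lists with wide spread numbered 6 to 13 in hippocampus and 4 to 9 in hypothalamus with a library left out. List levels moved by less than their SD in each of the 245 pairs of list and setting run. Leaving out 1 of 4 libraries cannot move their mean by as much as their SD. The pairs with a library left out were therefore bound to pass, and no conclusion on the stability of list levels is drawn from this count. Depth was unknown, so no limit on low genes can be given.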

Other observations

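Some pituitary genes were well expressed in hypothalamus, on values scaled within the table. Cga, the common subunit of glycoprotein hormones, stood at 322, 301, 176 and 19.7 FPKM in replicates 1 to 4, Pou1f1, a pituitary transcription factor, at 30.4, 19.3, 16.2 and 17.9, and Tshb at 6.04, 15.2, 12.5 and 1.99. Gh1, encoding growth hormone, stood at 0.072, 0.070, 0.15 and 0, and Prl, encoding prolactin, was listed at 0 in each. Of 12 pituitary markers, 6 passed the filter on low values and were compared between the separately made tables: 5 were higher in hypothalamus and 1 was neither. Their median difference after joint scaling was 2.64, with an adjusted p = 0.151 with an estimated correlation in limma's camera. It was 0.90 without a filter and 4.29 with a pseudocount of 0.1.

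Slc6a3, the dopamine transporter, stood at 0.389, 0.388, 3.93 and 9.96 FPKM in hypothalamus replicates 1 to 4 and Th at 20.6, 18.1, 35.2 and 55.1. Among other genes of dopamine neurons, Slc18a2, the vesicular monoamine transporter, lay between 12.9 and 14.4, Ddc stood at 8.25, 5.97, 6.50 and 9.22 and Ret at 13.8, 12.4, 16.0 and 19.6. Foxa1 stood at 0.772, 0.647, 1.99 and 2.05 and Nr4a2 at 3.79, 3.99, 6.76 and 6.59. Of red cell genes in hypothalamus, Hbb-b1 stood at 125, 38.0, 17.1 and 19.5 FPKM in replicates 1 to 4, Alas2 at 20.2, 14.8, 3.49 and 7.24 and Ahsp at 7.54, 4.55, 1.42 and 2.59, each highest in replicate 1. Slc4a1 was highest in replicate 2, at 1.54, 1.73, 0.15 and 0.48. Class II histocompatibility genes were highest in hypothalamus replicate 2, with RT1-Da at 20.8, 53.6, 16.0 and 18.6 FPKM and RT1-Db1 at 8.75, 33.7, 8.47 and 5.68. The dopamine and histocompatibility genes were chosen after their values had been seen.

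Some list members were in the table of a single tissue and entered no comparison. Scg2, encoding secretogranin, stood at 488 ± 32.2 FPKM in hypothalamus (SD, n = 4), Olig1 at 85.8 ± 8.36 and Olig2 at 24.0 ± 5.91. In hippocampus, Pkm stood at 140.3 ± 13.1 FPKM, Elovl1 at 33.1 ± 7.21 and Gria2 at 24.5 ± 16.8.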
